A study of Homo sapiens with 8 samples.

How the data were processed

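Human breast cancer cells of the lines MDA-MB-231 and MDA-MB-436 were transfected with siRNA against Fn14 or against GL2 (firefly luciferase) at 60 nmol/L with Lipofectamine, and RNA was taken 16 hours later, per the labels' protocols. Each of 8 arrays, on 8 slides, compared this RNA (Cy3) with RNA of untreated cells (Cy5). The dyes were not exchanged on any array, so siRNA against untreated cannot be told from a dye effect, while Fn14 against GL2 cancels a dye effect that is constant. The title of 1 array names the control siRNA GL1 and its other labels name it GL2, so it was taken as GL2.

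The submitters scanned the arrays and read them with Agilent Feature Extraction 8.1.1.1, per the file headers. The deposited scanner files hold the mean intensity and the local background intensity of each spot in each dye, per the file headers, and these are not normalized. Per the file headers, they also hold a log10 of untreated over siRNA after background subtraction and dye normalization by the scanner software. The deposited value table holds a linear ratio of siRNA over untreated, and its values equal the scanner's log10 with the sign turned, within 0.0005. That ratio has a median of 1 on each array.

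From the intensities, background was corrected by limma's normexp with an offset of 50, and loess was applied within each array, giving log2(siRNA / untreated). Spots of the same probe were averaged. Of 22153 features, 21073 spots of 20173 probes are not controls. A probe was kept when it stood well above background in either dye on at least 2 arrays, which left 19029 probes, and the probe with the highest mean intensity stood for its gene, which left 17381 genes. Control spots and spots marked by the scanner as outliers were left out, and saturated spots, at most 42 per array and dye, were kept. Gene names came from the accessions of the array's own annotation through RefSeq's gene table for the assembly GRCh38.p14, used for names alone: 16157 probes matched by accession, 1140 by symbol and 583 by an older symbol, and 2293 kept the name on the array. The genome build of the array design is not given in the sources used here, and no coordinates are printed.

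Differences were tested with limma 3.58.1 in R 4.3.3 by a fit of 4 group means (labelled line by siRNA, 2 arrays each, 4 residual degrees of freedom and a prior of 3.44), with Benjamini-Hochberg adjustment over all genes of a contrast and 0.05 as the threshold. All tests are two-sided. The contrasts were Fn14 against GL2 siRNA in each labelled line, over both and between them, each siRNA against untreated in each labelled line, the difference between labelled lines in siRNA against untreated, and untreated MDA-MB-436 against MDA-MB-231 from the Cy5 intensities, averaged per labelled line and replicate number. A total of 26 gene lists fixed before the data were examined were tested with limma's camera (preset correlation 0.01, and an estimated correlation beside it) and fry, adjusted over the 26 lists. Those reported cover TWEAK-Fn14 receptor signalling, NF-kB targets, interferon-stimulated genes, cholesterol and fatty acid synthesis, matrix proteolysis, integrins, G1/S, G2/M, p53 targets, apoptosis, ATF4 and unfolded proteins, heat shock, immediate early genes, TGF-beta targets, hypoxia, RNA interference, lysosome, ribosomal proteins, oxidative phosphorylation, epithelial and mesenchymal markers, and markers of luminal, leukocyte, and endothelial or neural cells.

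The rule for named genes was fixed before the data were examined. TNFRSF12A and TNFSF12 are given throughout. Further, of genes with a proper symbol that passed and whose arrays did not overlap between the sides (against untreated: the same sign on both arrays), the 12 with the largest change in each direction are named for Fn14 against GL2 over both labelled lines, for the difference between labelled lines in siRNA against untreated and for the untreated comparison, and 6 in each direction elsewhere, and where fewer than 5 passed, the 5 with the smallest p are named as not passing. Up to 4 genes of a list are added by the smallest p. The results of 1 list and of some genes that these rules pick are left out of the text and kept in all counts of calls.

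The replicate numbers were checked for pairing in the log ratios. Deviations of the Fn14 and GL2 arrays of the same labelled line and number from their group means correlated across genes at 0.138 in MDA-MB-231 and at 0.170 in MDA-MB-436, and with 2 arrays a group both numbers of a line give the same value. Since each exceeds 0.1, counts with the replicate number as a block are given where they change. TNFRSF12A and the number of named genes kept over both labelled lines are given as well. Other genes that lose their call are not named. In arrays labelled MDA-MB-436 the numbers part the arrays as the untreated profiles do. In those labelled MDA-MB-231, replicate 2 joins an Fn14 and a GL2 array of different untreated profiles. Their Cy5 intensities correlated at 0.939, against at least 0.992 within a set of like profiles. The check thus cannot tell pairing from profile, and fits with the block are given as alternatives alone. Of the arrays, 7 were scanned on 1 day and the array MDA-MB-231 Fn14 siRNA replicate 2 alone on another, so the fit with scan day as a block equals the fit of the 7 arrays, and no comparison lies within the other day.

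Signal limits the depth: between 87.0% and 93.7% of spots stood well above background in Cy3 and between 72.3% and 91.2% in Cy5. The fit was tested on simulated data for 17258 genes with 200 changed. Over both labelled lines it recovered 100% of 50 genes lowered by 1 on the log2 scale and 98% of 50 lowered by 0.5, with 7 false calls among 205, and for the difference between labelled lines 52% of 50 genes changed by 0.5. A G2/M list shifted by -0.2 was recovered by camera at an adjusted p of 0.011 with an estimated correlation. The simulated genes varied independently of one another, so this does not show the power of that test where genes of a list vary together. Each simulated gene also had the same spread on all 8 arrays, and no set of untreated profiles differed. The SD of the real log ratios ran from 0.106 to 0.215 by array. The recovery and the false calls thus hold for data that meet the fit's assumptions, and may not hold for these arrays.

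Alternatives, planned before the data were examined, were no background correction, median centring in place of loess, the scanner's log ratio, the deposited ratios, no filter and a strict filter on dim probes, every probe, arrays of the compared label alone, the replicate block (fixed, or random for siRNA against untreated), scan day as a block, an additive model, and leaving out each array in turn. Chosen after seeing the data were the untreated profile as a covariate, the arrays of each profile set alone, and leaving out the 3 arrays labelled otherwise than most arrays of their profile set. Figures were drawn with matplotlib 3.10.9.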

Results

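Expression was measured in MDA-MB-231 and MDA-MB-436, human breast cancer lines of the basal-like kind that lack hormone receptors, after siRNA against Fn14 or against GL2. Fn14 is the product of TNFRSF12A, the cell surface receptor for the cytokine TWEAK (TNFSF12), and GL2 is firefly luciferase, which human cells lack. Each of the 8 two-colour arrays held RNA of siRNA-treated cells in Cy3 and RNA of untreated cells in Cy5, and each of the 4 combinations of labelled line and siRNA had 2 arrays. The median Cy3 intensity of an array lay between 137.9 and 229.3, against a median background of 54 to 57. The median Cy5 intensity lay between 173.0 and 215.6 on 7 arrays and was 103.1 on the array labelled MDA-MB-436 Fn14 siRNA replicate 1, where 72.3% of spots stood well above background in Cy5, against 87.5% to 91.2% on the others. The number of arrays limits the precision of every value. The lines are named as labelled throughout, because the untreated profiles fell into sets of 5 and 3 arrays that cut across the labels, and 3 of the 8 arrays were out of place, that is labelled otherwise than most arrays of their set. Values are log2 ratios, and a difference of -1 is a fall to 50% of the level.

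The first comparison asks what Fn14 siRNA changed against a control siRNA with no human target. TNFRSF12A (probe A_23_P49338, the 1 probe of the gene) was lower with Fn14 siRNA on every array. Its log2 ratio of siRNA over untreated lay between -0.87 and -0.36 on the 4 Fn14 arrays and between 0.16 and 0.53 on the 4 GL2 arrays. By group, the mean was -0.47 ± 0.15 (SD, n = 2) with Fn14 and 0.48 ± 0.07 (SD, n = 2) with GL2 siRNA in arrays labelled MDA-MB-231, and -0.80 ± 0.09 (SD, n = 2) against 0.31 ± 0.21 (SD, n = 2) in those labelled MDA-MB-436. Over both labelled lines the difference was -1.03 (SE 0.08, limma adjusted p = 0.0026), which left 48.9% of the level with GL2 siRNA. The difference stayed past the threshold in all 22 alternatives, which are not independent of one another. Of these, the fit of the smaller profile set, with a lone Fn14 array, is not read as a test. Neither is the fit without the arrays out of place. The difference was -0.98 with scan day as a block and -1.03 with the replicate block. It was nearest the threshold at -0.72 with median centring (adjusted p = 0.043) and at -0.85 in the 5 arrays of the larger set of untreated profiles (adjusted p = 0.048). Its ligand TNFSF12 differed by 0.06 (SE 0.04, limma adjusted p = 0.47). The TNFSF12 probe was dim, at 6.4 to 6.6 (log2 intensity) in untreated RNA against 10.9 to 11.2 for TNFRSF12A, so a change could be missed.

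Against GL2 siRNA, Fn14 siRNA lowered a set of genes as far as its target and raised HMGA2. With TNFRSF12A at -1.03, the genes named as lowest were IL11, a cytokine of the interleukin-6 family, at -1.36 (SE 0.23), RAC2 at -1.14 (SE 0.05), DAZAP2 at -1.03 (SE 0.06) and COPRS (HSA272196 on the array), a partner of the histone methyltransferase PRMT5, at -1.01 (SE 0.04). EI24, MAGED2, OIP5 (a centromere protein), STAMBP (a deubiquitinase), RIOK1 (a kinase of ribosome maturation), ATP5PB (ATP5F1 on the array) and CDKN2D (an inhibitor of cyclin D-dependent kinases) lay between -0.83 and -0.77. EI24 had values on 3 arrays of each siRNA and ATP5PB on 3 of the GL2 arrays. HMGA2, an architectural chromatin protein, was higher by 1.08 (SE 0.10). DYNC2LI1 (D2LIC on the array), a dynein chain of cilia, E2F5, PPIC, TUSC2, SLC18B1 (C6orf192 on the array), KIF9, SNF1LK, AMPD3, IFT43 (MGC16028 on the array), a protein of cilia transport, OSCP1 (NOR1 on the array) and TECPR2 (KIAA0329 on the array) were higher by 0.69 to 0.47. For each of these 24 genes, every Fn14 array lay beyond every GL2 array, and limma's adjusted p lay between 0.00023 and 0.043.

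**Figure D1:**
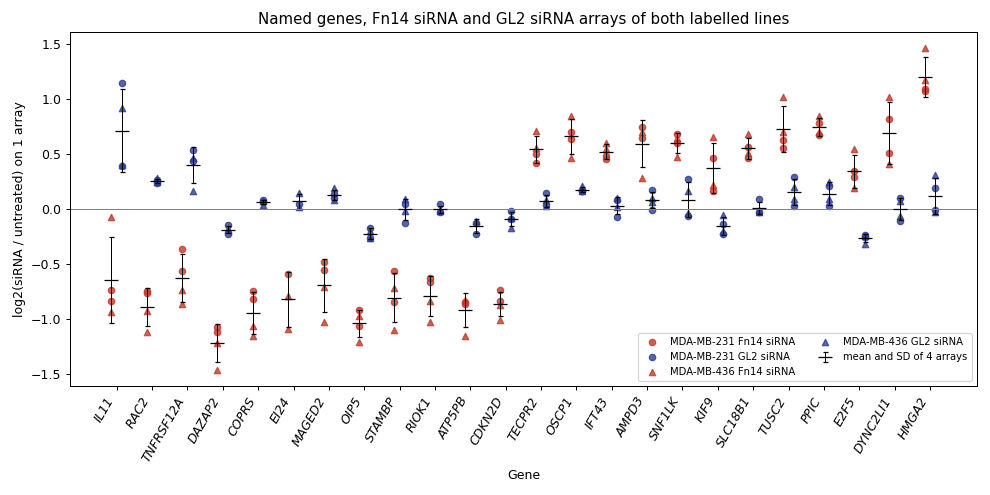
The vertical axis gives log2(siRNA / untreated) on 1 array and the horizontal axis the 24 genes named for Fn14 against GL2 siRNA over both labelled lines, with a point per array and the mean and SD over the arrays of each siRNA (EI24 and ATP5PB have missing arrays). The Fn14 and GL2 arrays do not overlap for any of these genes, which were picked by that rule, and TNFRSF12A lies between -0.87 and -0.36 with Fn14 and between 0.16 and 0.53 with GL2 siRNA.

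In all, 631 of 17372 genes differed over both labelled lines (limma, Benjamini-Hochberg adjusted p under 0.05), 349 higher and 282 lower with Fn14 siRNA, of which 32 differed by more than 1.5-fold (4 higher, 28 lower). With median centring in place of loess, 586 genes were higher and 10 lower. The count was 405 with the replicate block, 63 with scan day as a block (18 higher, 45 lower), 208 from the scanner's log ratio and 206 from the deposited ratios. It was 76 or 63 without MDA-MB-231 Fn14 replicate 1 or 2, 140 or 52 without MDA-MB-231 GL2 replicate 1 or 2, 2461 or 2421 without MDA-MB-436 Fn14 replicate 1 or 2, and 63 or 44 without MDA-MB-436 GL2 replicate 1 or 2. Without the 3 arrays whose untreated profile was out of place it was 985, but every fit without them has 1 residual degree of freedom, from the MDA-MB-231 Fn14 pair.

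Over both labelled lines, of 34 measured genes of G2/M and mitosis, 9 fell and 0 rose, or 17 and 0 adjusted over the list alone. CENPF, a kinetochore protein, fell by 0.65 on the log2 scale (SE 0.05), BIRC5 (survivin) by 0.53 (SE 0.10), TPX2, a spindle protein, by 0.39 (SE 0.05) and the cyclin CCNB2 by 0.30 (SE 0.04). The median of the list was -0.21 (limma's camera, adjusted p = 2.6e-12 with the preset correlation and 0.12 with an estimated correlation), and it was 0.04 with median centring, where CCNB2 turned to 0.01. Of 29 genes of G1/S and DNA replication, 4 fell and 0 rose, or 9 and 0 adjusted over the list alone. These were the uracil glycosylase UNG at -0.61 (SE 0.11), the flap endonuclease FEN1 at -0.34 (SE 0.06), the transcription factor E2F1 at -0.24 (SE 0.05) and the ribonucleotide reductase subunit RRM1 at -0.23 (SE 0.04). The list's median of -0.08 (camera adjusted p = 6.1e-06, and 0.12 with an estimated correlation) turned to 0.14 with median centring, as E2F1 turned to 0.05 and RRM1 to 0.09.

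Of 25 p53 target genes, 0 passed over all genes and 4 were lower adjusted over the list alone, with a median of -0.03 (camera adjusted p = 0.027, and 0.19 with an estimated correlation) that turned to 0.05 with median centring. DDB2 was at -0.24 (SE 0.06) and CDKN1A, the inhibitor p21, at -0.15 (SE 0.04), neither past the test. Of 25 genes of oxidative phosphorylation, SDHB of complex II rose by 0.20 (SE 0.04), ATP5PO of ATP synthase rose by 0.23 (SE 0.04) and 0 fell, or 7 and 0 adjusted over the list alone. Their median was 0.14 (camera adjusted p = 1.5e-05, and 0.12 with an estimated correlation) and 0.42 with median centring, while ATP5PB, which is not on the list, was at -0.78.

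**Figure D2:**
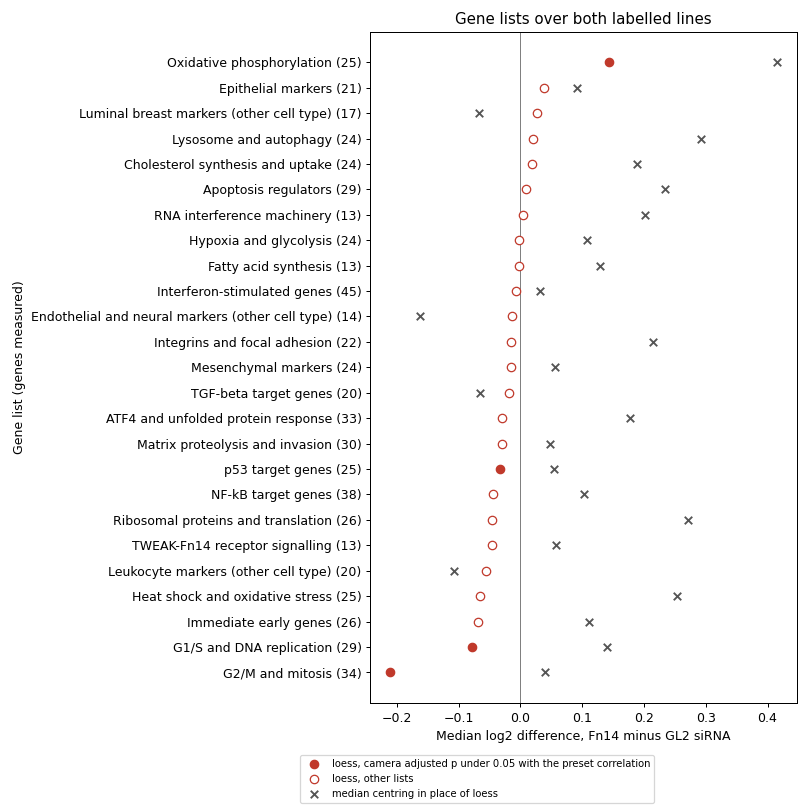
The horizontal axis gives the median log2 difference, Fn14 minus GL2 siRNA over both labelled lines, of 25 gene lists on the vertical axis, with circles for loess (filled where limma's camera passed with its preset correlation) and crosses for median centring. The filled circles run from -0.21 for G2/M and mitosis to 0.14 for oxidative phosphorylation, and the 3 filled circles below 0 have crosses above 0.

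Of 38 measured NF-kB target genes, 3 rose and 2 fell over both labelled lines, or 4 and 2 adjusted over the list alone. Their median was -0.05 (camera adjusted p = 0.42), and it was 0.10 with median centring. Resampling the genes, with the arrays held fixed, gave a 95% interval of -0.082 to -0.006 for that median of -0.05, which leaves out the spread between arrays. The cytokines IL6 at -0.53 (SE 0.10) and CSF2 at -0.40 (SE 0.05) fell, and the inhibitor NFKBIA at 0.25 (SE 0.05) and the subunit RELB at 0.19 (SE 0.04) rose. Under both labels, IL6 and CSF2 were higher with GL2 siRNA than untreated, with the dye confounded (values below). Their falls are thus measured from that level. In the TWEAK-Fn14 list of 13 genes, TNFRSF12A fell and no other gene passed, with IKBKG at -0.21 (SE 0.06). Of 30 genes of matrix proteolysis and invasion, 1 passed, the urokinase PLAU at -0.51 (SE 0.05), and its receptor PLAUR was at -0.23 (SE 0.06), not past the test. The remaining lists had a camera adjusted p between 0.086 and 0.96. With median centring 5 of them passed as higher, with medians of 0.29 (lysosome), 0.27 (ribosomal), 0.25 (heat shock), 0.19 (cholesterol) and 0.18 (ATF4), so that camera called 6 lists higher and 0 lower there, against 1 and 4 with loess. Among apoptosis regulators (29 measured, 3 higher and 0 lower), the genes that rose included DIABLO by 0.22 (SE 0.04) and BIK by 0.21 (SE 0.04). In hypoxia and glycolysis (24 measured), the mitophagy receptor BNIP3L fell by 0.54 (SE 0.05) and the prolyl hydroxylase EGLN1 rose by 0.37 (SE 0.05).

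From 1 to 3 genes passed in each of 9 further lists. In cholesterol synthesis (24 measured), 1 gene was higher and 2 were lower, among them ACAT2 at -0.29 (SE 0.05, but 0.02 with median centring) and HSD17B7 at 0.23 (SE 0.05). The TGF-beta list (20 measured) had BAMBI, a decoy receptor, at 0.42 (SE 0.05), the immediate early list (26) MYC at 0.27 (SE 0.05), and the interferon-stimulated list (45) OASL at -0.60 (SE 0.11). The integrin and focal adhesion list (22) had ILK at -0.35 (SE 0.06), the ATF4 list (33) DDIT4 at -0.31 (SE 0.04), and the heat shock list (25) DNAJB1 at -0.26 (SE 0.05, but 0.01 with median centring). The ribosomal list (26) had RPS6 at -0.40 (SE 0.08) and the lysosome and autophagy list (24) ATG12 at -0.22 (SE 0.04, but 0.05 with median centring). In fatty acid synthesis (13 measured), RNA interference machinery (13), epithelial markers (21) and mesenchymal markers (24), 0 genes passed over all genes, and their medians were 0.00, 0.00, 0.04 and -0.02. Of the markers of other cell types, the leukocyte list (20) had CD14 higher by 0.20 (SE 0.04), and the luminal breast list (17) and the endothelial and neural list (14) had 0 genes past the test, with medians of -0.06, 0.03 and -0.01.

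The replicate block kept 41 of the 54 genes given above as passing, scan day as a block kept 15, and the scanner's log ratio kept 26. Median centring kept 25 and turned 6, and the 5 arrays of the larger profile set kept 22. The Fn14 and GL2 arrays are spread unevenly over the profile sets, and the fit with the untreated profile as a covariate kept 48. Without MDA-MB-231 Fn14 replicate 1 or 2, 16 or 15 passed, without MDA-MB-231 GL2 replicate 1 or 2, 26 or 15, without MDA-MB-436 Fn14 replicate 1 or 2, 54 in each case, and without MDA-MB-436 GL2 replicate 1 or 2, 14 in each case. TNFRSF12A, RAC2, DAZAP2, COPRS, RIOK1, CDKN2D, HMGA2 and IFT43 stayed past the threshold in the same direction in all 22 alternatives. Among these, the fit of the smaller profile set has a lone Fn14 array and tests nothing. The fit without the arrays out of place is not read as a test either. Nor are the 22 independent, as scan day as a block repeats leaving out MDA-MB-231 Fn14 replicate 2. The deposited ratios likewise nearly repeat the scanner's log ratio.

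In arrays labelled MDA-MB-231, 26 genes were lower with Fn14 than with GL2 siRNA and 0 were higher, by limma, with 1426 genes at an unadjusted p under 0.05. Both Fn14 arrays of this label lay in the larger set of untreated profiles, whereas the GL2 arrays lay in different sets. Each ratio is taken against untreated RNA of the same set, but a response that differs between the sets would enter this comparison. RAC2 was at -1.0 (SE 0.07), TNFRSF12A at -0.95 (SE 0.11, adjusted p = 0.043, 51.8% of the GL2 level), DAZAP2 at -0.91 (SE 0.08), COPRS at -0.86 (SE 0.06), OIP5 at -0.78 (SE 0.09) and TSR1, a factor of ribosome assembly (FLJ10534 on the array), at -0.75 (SE 0.09). No higher gene passed. Those with the smallest unadjusted p included MRS2 at 0.38 (SE 0.05), VIPAS39 at 0.40 (SE 0.05), HMGA2 at 0.99 (SE 0.14) and RECK at 0.53 (SE 0.07), none of which passed. Camera put 6 lists lower (among them G2/M, G1/S, ATF4, matrix proteolysis and p53 targets) and oxidative phosphorylation higher, and 0 of these with an estimated correlation, where the smallest adjusted p was 0.10. The G2/M median was -0.21 and stayed below 0 with median centring at -0.10, while the G1/S median of -0.11 turned to 0.01 and the ATF4 median of -0.06 to 0.04. The medians of matrix proteolysis and p53 targets went from -0.06 and -0.08 to -0.04 and -0.03, no longer past the test, that of oxidative phosphorylation went from 0.10 to 0.23, and the lysosome list passed as higher at 0.13.

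That count was 4 with the replicate block (1 higher, 3 lower, 3 of them among the 26) and 3 with scan day as a block (3 higher, 0 lower, 0 of them among the 26). It was 0 with median centring, from the scanner's log ratio and from the deposited ratios. Leaving out MDA-MB-231 Fn14 replicate 1 or 2 gave 0 or 3 (the same 3 higher, 0 lower), and MDA-MB-231 GL2 replicate 1 or 2 gave 0 or 1 (lower, not among the 26). Leaving out either MDA-MB-436 Fn14 array gave 321 (143 higher, 178 lower) and either MDA-MB-436 GL2 array 0. TNFRSF12A no longer passed without any 1 of the 4 arrays labelled MDA-MB-231, at -1.05 or -0.84 without Fn14 replicate 1 or 2 and at -1.0 or -0.90 without GL2 replicate 1 or 2. Nor did it pass, at -0.95, without either MDA-MB-436 GL2 array or with the replicate block, or at -0.84 with scan day as a block, -0.81 with median centring or -0.97 from the scanner's log ratio. A fit of the arrays of this label alone called 115 genes (24 higher, 91 lower), among them the 26.

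In arrays labelled MDA-MB-436, 161 genes were higher and 115 lower with Fn14 than with GL2 siRNA, 276 in all by limma, and 911 were higher and 8 lower with median centring. RAC2 was at -1.28 (SE 0.07), COPRS at -1.16 (SE 0.06), DAZAP2 at -1.15 (SE 0.08), TNFRSF12A at -1.11 (SE 0.11, adjusted p = 0.015, 46.2% of the GL2 level), EI24 at -1.02 (SE 0.11) and MAGED2 at -1.0 (SE 0.10). HMGA2 rose by 1.17 (SE 0.14), TUSC2 by 0.72 (SE 0.12), E2F5 by 0.65 (SE 0.11), SLC18B1 by 0.61 (SE 0.08), PPIC by 0.61 (SE 0.09) and TBC1D7, a subunit of the TSC complex, by 0.59 (SE 0.09). Camera put 4 lists lower, among them G2/M (median -0.19), G1/S (-0.08) and leukocyte markers (-0.09), and oxidative phosphorylation (0.22) higher, and 0 of these with an estimated correlation, where the smallest adjusted p was 0.18. With median centring the medians were 0.23 for G2/M and -0.11 for leukocyte markers, both no longer past the test, 0.34 for G1/S, past it as higher (adjusted p = 0.023), and 0.66 for oxidative phosphorylation. In all, 7 lists then passed as higher and 0 as lower.

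This count was 45 with the replicate block (11 higher, 34 lower) and 12 with scan day as a block (0 higher, 12 lower). It was 27 from the scanner's log ratio (7 higher, 20 lower) and from the deposited ratios, and 0 with the arrays of this label alone. Leaving out either MDA-MB-231 Fn14 array gave 12, either MDA-MB-231 GL2 array 18, MDA-MB-436 Fn14 replicate 1 or 2 gave 2358 or 2065, and MDA-MB-436 GL2 replicate 1 or 2 gave 2 or 0. Without the 3 arrays out of place, 1 array of each siRNA is left under this label, so that fit is not read as a test. TNFRSF12A no longer passed at -1.27 or -0.96 without MDA-MB-436 GL2 replicate 1 or 2. Nor did it, at -1.11, without any 1 of the 4 arrays labelled MDA-MB-231, with scan day as a block or with the arrays of this label alone, or at -0.64 with median centring.

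Whether the labelled lines differed in their response to Fn14 siRNA was tested directly. Since arrays of each label lie in both sets of untreated profiles, this compares labels and does not measure a difference between the lines. By limma 0 of 17372 genes passed, with 811 at an unadjusted p under 0.05, and camera put 0 lists past the test (fry 1, RNA interference machinery). TNFRSF12A differed by -0.17 (SE 0.16, limma adjusted p = 0.97) in MDA-MB-436 minus MDA-MB-231. The smallest p among higher differences belonged to DDIT4 at 0.50 (SE 0.09), MCRIP2 at 0.37 (SE 0.07), PHB2 at 0.39 (SE 0.07), AFG3L1P at 0.37 (SE 0.07) and WDR46 at 0.38 (SE 0.07), and among lower ones to ATRAID at -0.38 (SE 0.07), FCHSD2 at -0.34 (SE 0.07), OAZ1 at -0.46 (SE 0.09), SRD5A1 at -0.42 (SE 0.09) and RECQL at -0.32 (SE 0.07), none past the test. Of the 26 genes called in MDA-MB-231, 24 were called in MDA-MB-436 as well, where independent lists would share 0.413, and 26 had the same sign. Both comparisons took each gene's spread from the same fit. The lists are therefore not independent, and 0.413 does not measure the overlap without a shared change. Across genes, which are not independent replicates, the differences of both labelled lines had Pearson's r of 0.574 and a Spearman correlation of 0.448. The count was 159 without MDA-MB-436 Fn14 replicate 1, and it was 1 without MDA-MB-231 Fn14 replicate 2 or with scan day as a block. With median centring camera put 10 lists higher, and without MDA-MB-436 GL2 replicate 1 it put 1 list past the test. Without the 3 arrays out of place it put 2 past it (1 higher, 1 lower).

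GL2 siRNA against untreated cells asks what transfection with a control siRNA changed, with the dye and the treatment confounded, since Cy3 held the siRNA RNA on every array. Of 38 NF-kB target genes, 11 rose in MDA-MB-231 and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 2.5e-10, and 0.15 with an estimated correlation). In MDA-MB-436, 4 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 2.5e-09, and 0.15 with an estimated correlation). With median centring these medians were 0.12 and 0.11. IL6 rose by 0.74 (SE 0.10) and 0.72 (SE 0.10), CSF2 by 0.50 (SE 0.05) and 0.44 (SE 0.05), and the adhesion molecule ICAM1 by 0.44 (SE 0.05) and 0.33 (SE 0.05) in MDA-MB-231 and MDA-MB-436. TNFRSF12A itself was at 0.48 (SE 0.08, adjusted p = 0.027) in MDA-MB-231 and at 0.31 (SE 0.08, adjusted p = 0.12) in MDA-MB-436. The former no longer passed with scan day as a block (adjusted p = 0.064), with median centring (0.30, adjusted p = 0.44), or from the scanner's log ratio or the deposited ratios (0.49, adjusted p = 0.065). Nor did it pass without any 1 array except those of MDA-MB-436 Fn14 (0.43 to 0.53, adjusted p = 0.052 to 0.33) or without the 3 arrays out of place (0.43, adjusted p = 0.061).

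Beyond these, the largest rises with GL2 siRNA in MDA-MB-231 were those of the chemokine CXCL1 at 1.01 (SE 0.20), UBE2M at 1.01 (SE 0.16), SDC4 at 0.80 (SE 0.12), ANXA6 at 0.73 (SE 0.10) and TSR2 at 0.65 (SE 0.05), and the largest falls those of ARL6IP1 at -0.66 (SE 0.06), thymidylate synthase (TYMS) at -0.51 (SE 0.04), LSM6 at -0.49 (SE 0.08), DLGAP4 at -0.48 (SE 0.04), CKS2 at -0.48 (SE 0.09) and UQCR10 at -0.46 (SE 0.08). In MDA-MB-436, ANXA6 rose by 0.63 (SE 0.10), AKT1 by 0.55 (SE 0.07), PSAP by 0.54 (SE 0.06), TSR2 by 0.53 (SE 0.05) and PIR by 0.51 (SE 0.07), and ARL6IP1 was at -0.69 (SE 0.06), TYMS at -0.53 (SE 0.04), OAT at -0.51 (SE 0.07), RAP1B at -0.47 (SE 0.06) and H2AZ2 at -0.42 (SE 0.05). Of 34 genes of G2/M, 3 fell and 1 rose in MDA-MB-231 (median -0.09) and 0 passed in MDA-MB-436 (median -0.09), with camera adjusted p of 0.0017 and 0.0003, and 0.21 and 0.19 with an estimated correlation. With median centring these medians were -0.24 and -0.19. The falls were CKS2, CCNB1 at -0.30 (SE 0.06) and PTTG1 at -0.23 (SE 0.03), and AURKB rose by 0.31 (SE 0.06). Camera also put TWEAK-Fn14, lysosome, hypoxia and glycolysis, matrix proteolysis and apoptosis genes higher in arrays of both labels, with medians from 0.05 to 0.14 and an adjusted p of at least 0.15 with an estimated correlation. With median centring the medians of the lysosome list turned to -0.01 in both, those of the apoptosis list to -0.03 and 0.00 and that of the hypoxia list in MDA-MB-231 to 0.00. Those of TWEAK-Fn14 fell to 0.07 and 0.06 and those of matrix proteolysis to 0.03 in both, and none of these 5 lists passed in either label. Camera put 9 lists higher and 1 lower in each label with loess, and 1 higher (NF-kB) and 4 lower with median centring. These were G2/M, G1/S (-0.18 and -0.14), ribosomal proteins (-0.29 and -0.26) and oxidative phosphorylation (-0.25 and -0.18).

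By limma, 715 genes differed in MDA-MB-231 (475 higher, 240 lower) and 171 in MDA-MB-436 (103 higher, 68 lower). Each count was 0 with median centring, from the scanner's log ratio and from the deposited ratios, and with scan day as a block the counts were 63 and 0. The MDA-MB-231 count was 63 without either MDA-MB-231 Fn14 array, 0 or 1 without MDA-MB-231 GL2 replicate 1 or 2, 2933 without either MDA-MB-436 Fn14 array and 0 without either MDA-MB-436 GL2 array. The MDA-MB-436 count was 1799 without either MDA-MB-436 Fn14 array and 0 without any 1 of the other 6 arrays, and 0 with the arrays of this label alone.

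Fn14 siRNA against untreated cells asks what the knockdown with its transfection changed, again confounded with the dye. Of 34 genes of G2/M, 21 fell in MDA-MB-231 and 0 rose (26 and 0 adjusted over the list alone, median -0.29), and in MDA-MB-436 20 fell and 0 rose (21 and 0, median -0.30). Camera's adjusted p was 8.9e-15 and 6.5e-09, and 0.11 and 0.22 with an estimated correlation. CENPF was at -0.88 (SE 0.05) and -0.85 (SE 0.05). Of 29 genes of G1/S, 9 fell in MDA-MB-231 and 12 in MDA-MB-436, and 0 rose, with medians of -0.13 and -0.16 (camera adjusted p = 2.2e-05 and 0.00043, and 0.17 and 0.22 with an estimated correlation), and TYMS was at -0.76 (SE 0.04) and -0.61 (SE 0.04). With median centring the medians in MDA-MB-436 turned to 0.05 for G2/M and 0.17 for G1/S, while those in MDA-MB-231 stayed at -0.31 and -0.16. NF-kB target genes rose in both, 10 of 38 with 0 falls in each (medians 0.15 and 0.18), with a camera adjusted p of 8.4e-06 and 0.0022, and of 0.23 and 0.34 with an estimated correlation. ICAM1 rose by 0.64 (SE 0.05) and 0.57 (SE 0.05) and RELB by 0.45 (SE 0.04) and 0.44 (SE 0.04). Lysosome genes were also higher in both (medians 0.15 and 0.14), apoptosis regulators in MDA-MB-231 (0.10) and oxidative phosphorylation in MDA-MB-436 (0.12), by camera with the preset correlation, with an adjusted p of at least 0.17 with an estimated correlation. With median centring the medians in MDA-MB-436 rose to 0.47 (NF-kB), 0.42 (lysosome) and 0.46 (oxidative phosphorylation), and in MDA-MB-231 they were 0.14 (NF-kB), 0.12 (lysosome) and 0.07 (apoptosis regulators, adjusted p = 0.072). Further lists passed there, the ribosomal list as lower in MDA-MB-231 (-0.23) and the heat shock (0.28), ATF4 (0.26) and cholesterol (0.24) lists as higher in MDA-MB-436.

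Of the genes past the test, 78 lay lower than TNFRSF12A in MDA-MB-231 and 21 in MDA-MB-436. TNFRSF12A was at -0.47 (SE 0.08, limma adjusted p = 0.014) in MDA-MB-231 and -0.80 (SE 0.08, limma adjusted p = 0.0014) in MDA-MB-436. It no longer passed in MDA-MB-231 at -0.57 or -0.36 without Fn14 replicate 1 or 2 or at -0.36 with scan day as a block. With median centring it passed in neither, at -0.50 and -0.44. The genes named as highest in MDA-MB-231 were HMGA2 at 1.07 (SE 0.10), the heme oxygenase HMOX1 at 0.97 (SE 0.11), EIF4EBP2 at 0.88 (SE 0.10), the chemokine CCL2 at 0.83 (SE 0.12), RRAD at 0.76 (SE 0.13) and TMED9 at 0.73 (SE 0.14). The lowest were DAZAP2 at -1.10 (SE 0.06), OIP5 at -0.99 (SE 0.06), CENPF and the histone H4 genes H4C3 at -1.08 (SE 0.25), H4C13 at -0.99 (SE 0.23) and H4C9 at -0.94 (SE 0.23), whose near-identical copies a probe cannot tell apart with certainty. In MDA-MB-436 HMGA2 was at 1.31 (SE 0.10), TBC1D7 at 0.92 (SE 0.06), PSAP at 0.89 (SE 0.06), TUSC2 at 0.86 (SE 0.09), PPT2 at 0.85 (SE 0.06) and EIF4EBP2 at 0.81 (SE 0.10), and DAZAP2 at -1.35 (SE 0.06), the chromatin protein HMGB2 at -1.12 (SE 0.11), COPRS at -1.11 (SE 0.04), OIP5 at -1.09 (SE 0.06), RAC2 at -1.02 (SE 0.05) and the proliferation marker MKI67 at -1.0 (SE 0.25).

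By limma, 2125 genes differed in MDA-MB-231 (1251 higher, 874 lower) and 3856 in MDA-MB-436 (2173 higher, 1683 lower), against 2 higher with 3 lower and 3426 higher with 688 lower under median centring. The MDA-MB-231 count was 28 with scan day as a block, 1156 from the scanner's log ratio and 1154 from the deposited ratios, and the MDA-MB-436 count was 2955 with scan day as a block and 1239 with the arrays of this label alone. Without MDA-MB-231 Fn14 replicate 1 or 2 the MDA-MB-231 count was 6 or 28, without either MDA-MB-231 GL2 array 1341, without either MDA-MB-436 Fn14 array 4492 and without either MDA-MB-436 GL2 array 1164.

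The response to siRNA against untreated cells, over both siRNAs, was also compared between the labelled lines. This too compares labels that cut across the profile sets, and does not measure a difference between the lines. By limma 0 genes passed, with 1486 at an unadjusted p under 0.05, and 0 lists passed by camera (fry 1, RNA interference machinery). Nearest were CCNH at 0.30 (SE 0.05), RPL35A at 0.21 (SE 0.04), MAN2A1 at 0.21 (SE 0.04), MED4 at 0.19 (SE 0.04) and ETV4 at 0.18 (SE 0.03), higher in MDA-MB-436. Nearest among lower ones were MAP3K10 at -0.45 (SE 0.06), PTMS at -0.21 (SE 0.03), WNT10A at -0.28 (SE 0.05), ATRAID at -0.21 (SE 0.04) and KCNH6 at -0.37 (SE 0.07), none past the test. The count was 266 without MDA-MB-436 Fn14 replicate 1, 2 without MDA-MB-436 Fn14 replicate 2, and 1 without MDA-MB-231 Fn14 replicate 2 or with scan day as a block, and it was 220 without the 3 arrays out of place. Camera put 1 list past the test without either MDA-MB-231 GL2 array or MDA-MB-436 Fn14 replicate 1, and 2 without MDA-MB-436 GL2 replicate 2. It put 8 lists higher with median centring, and 4 past the test (1 higher, 3 lower) without the 3 arrays out of place, where MDA-MB-436 has a lone array per siRNA.

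Untreated MDA-MB-436 against untreated MDA-MB-231 compares the Cy5 channel by label. Since arrays of each label lie in both profile sets, it does not measure the difference between the lines. By limma 0 of 17381 genes passed, with 92 at an unadjusted p under 0.05, and 0 lists passed by camera or fry. Nearest were CETN1 at 0.52 (SE 0.08), SMPD3 at 0.52 (SE 0.10), CHST13 at 0.51 (SE 0.09), ZNF385B at 0.45 (SE 0.09) and FGD1 at 0.42 (SE 0.09), higher in MDA-MB-436. Nearest among lower ones were LAMB2 at -0.32 (SE 0.09), JUN at -0.31 (SE 0.08), PA2G4 at -0.30 (SE 0.08), RPL19 at -0.29 (SE 0.08) and PRKRIP1 at -0.29 (SE 0.08), none past the test. TNFRSF12A stood at 10.9 to 11.2 (log2 intensity) in untreated RNA of all 8 arrays. Leaving out either MDA-MB-436 replicate number put 1 list past the test.

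The untreated profiles did not divide along the labels. They fell into a set of 5 arrays (MDA-MB-231 Fn14 replicates 1 and 2 and GL2 replicate 1, MDA-MB-436 Fn14 replicate 1 and GL2 replicate 1) and a set of 3 (MDA-MB-231 GL2 replicate 2, MDA-MB-436 Fn14 replicate 2 and GL2 replicate 2). The correlation across 17258 genes lay between 0.992 and 0.998 within a set and between 0.937 and 0.944 across sets, for values across genes, which are not independent replicates. Among genes picked after their values were seen, keratin 19 (KRT19) stood at 13.5 to 13.8 (log2 intensity) on the 5 arrays and at 8.3 to 8.8 on the 3, and the cell cycle inhibitor CDKN2A at 8.4 to 9.0 and 11.8 to 11.9. Each of the 4 pairs of replicates except the MDA-MB-231 Fn14 pair held an array of each set.

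**Figure D3:**
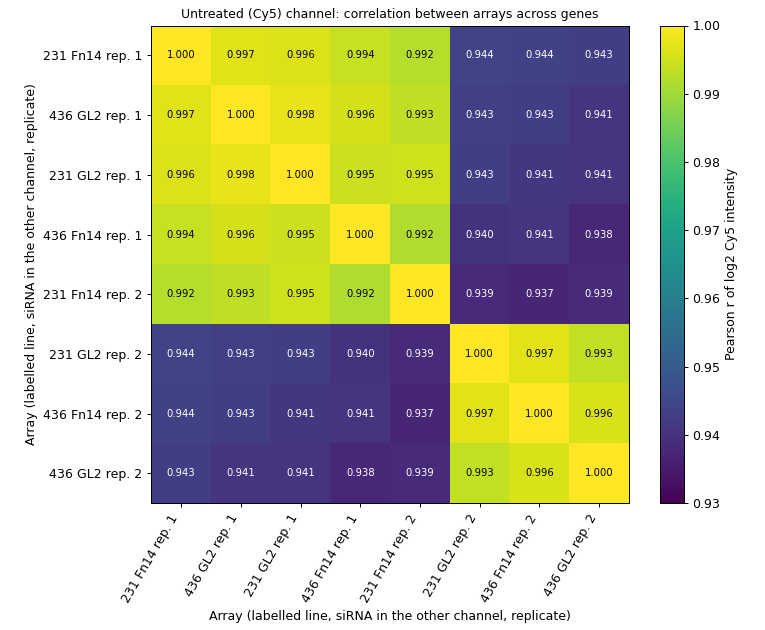
Each cell gives Pearson's r, across genes, of the log2 Cy5 intensity of untreated RNA between the arrays named on both axes. The values lie between 0.992 and 0.998 within the sets of 5 and 3 arrays and between 0.937 and 0.944 across them, and each set holds arrays of both labelled lines.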

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

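The signal over background, the 4 residual degrees of freedom and the dye that was never exchanged limit all results, and leaving out 1 array leaves a group with a lone array, which is assumed to vary like the others. Without the 3 arrays out of place, 1 residual degree of freedom is left, from the MDA-MB-231 Fn14 pair, and MDA-MB-436 keeps 1 array per siRNA, so counts from that fit are given and not read as tests. Leaving out the 3 arrays out of place and the fits by profile set were chosen after seeing the data. Where a count or a call moved, the cause was not tested, except that fits of fewer arrays have fewer degrees of freedom. Over all alternatives, named genes that had passed stayed past the test 2033 times, no longer passed 1458 times and turned 8 times, and lists that had passed did so 454, 106 and 8 times, by the direction of camera's test. The sign of the median is another matter: with median centring it changed in 16 called lists over all contrasts, in 9 of them with camera's direction unchanged.

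Genes called for Fn14 against GL2 in MDA-MB-231 were 0 with median centring, the scanner's log ratio and the deposited ratios, 115 with its arrays alone, 3 with scan day as a block and 0 to 321 leaving out 1 array. In MDA-MB-436 they were 919, 27, 27, 0, 12 and 0 to 2358, and 933 without the 3 arrays out of place. Over both labelled lines they were 208 (scanner), 206 (deposited), 63 (scan day), 44 to 2461 leaving out 1 array, 985 without the 3 arrays out of place, 63 in the set of 5 arrays and 5484 in the set of 3, which has 1 Fn14 array against 2 GL2 arrays and 1 residual degree of freedom, and so tests nothing. The difference between labelled lines gave 1 with scan day and 0 to 159 leaving out 1 array. GL2 against untreated gave 0 in both labelled lines with median centring, scanner and deposited ratios. Scan day gave 63 and 0, the labelled line alone 2334 and 0, leaving out 1 array 0 to 2933 and 0 to 1799, and leaving out the 3 arrays 59 in MDA-MB-231. Fn14 against untreated in MDA-MB-231 gave 5 (median centring), 1156 (scanner), 1154 (deposited), 3922 (alone), 28 (scan day), 3970 (without the 3 arrays) and 6 to 4492, and in MDA-MB-436 1239 (alone). The line difference against untreated gave 1 with scan day, 220 without the 3 arrays and 0 to 266.

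With the replicate block the counts for Fn14 against GL2 were 405 over both labelled lines, 4 in MDA-MB-231 and 45 in MDA-MB-436, and TNFRSF12A in MDA-MB-231, at -0.95, no longer passed. It kept 41 of the 54 genes named as passing over both labelled lines, and the paired fit moved no other count of calls by over 1.5 times. Counts at an unadjusted p are not covered by this.

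TNFRSF12A in MDA-MB-231 no longer passed at -0.94 with no background correction, -0.81 with median centring, -0.97 with the scanner's and the deposited ratios, -0.84 with scan day and, at -1.05 to -0.84, without any 1 of 6 arrays, while it passed at -0.95 without either MDA-MB-436 Fn14 array. In MDA-MB-436 it no longer passed at -0.64 with median centring, -1.11 with its arrays alone or with scan day, nor, at -1.27 to -0.96, without any 1 of the same 6 arrays. Lists called were 0 with an estimated correlation in each contrast. Median centring called 6 over both (6 higher, 0 lower, 1 shared, against 1 and 4 with loess), 7 in MDA-MB-436 (7 higher, 0 lower, 2 shared, against 1 and 4), 3 in MDA-MB-231 (2 higher, 1 lower), 10 for the difference between labelled lines in Fn14 against GL2, 5 and 5 with GL2 against untreated (1 higher and 4 lower in each, against 9 and 1) and 8 for the line difference against untreated. Of the 2 shared in MDA-MB-436, G1/S had turned from lower to higher. Fry called 1 for each line difference and 8 and 10 for Fn14 against untreated. Without the 3 arrays the lists called were 8 over both, 2 and 4 for the line differences and 10 for Fn14 against untreated in MDA-MB-436. Leaving out 1 array called 5 to 8 over both, 0 to 1 and 0 to 2 for the line differences and 0 to 1 for untreated.

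With median centring these genes turned. Over both labelled lines, ACAT2 was at 0.015, RRM1 0.086, E2F1 0.047, CCNB2 0.011, DNAJB1 0.011 and ATG12 0.050, and with GL2 against untreated in MDA-MB-231 TPI1 was at -0.077 and RPS3 at -0.026. Camera's direction turned for the following lists, some of whose medians lay beyond 0 already. Their medians over both were then 0.19 (cholesterol), 0.14 (G1/S), 0.039 (G2/M), 0.18 (ATF4), 0.25 (heat shock) and 0.27 (ribosomal), and in MDA-MB-436 0.24, 0.34, 0.23, 0.35, 0.40 and 0.48. They were 0.30 for heat shock in the difference between labelled lines, -0.073 (ATF4) and -0.015 (lysosome) with GL2 against untreated in MDA-MB-231, 0.17 (G1/S) and 0.28 (heat shock) with Fn14 against untreated in MDA-MB-436, and 0.20 (G1/S), 0.23 (heat shock) and 0.29 (ribosomal) for the line difference against untreated. Of called lists, the median alone changed sign for p53 targets over both (0.054), for G1/S (0.0091) and ATF4 (0.045) with Fn14 against GL2 in MDA-MB-231, for integrins (-0.0095), apoptosis (-0.026) and hypoxia (-0.0040) with GL2 against untreated in MDA-MB-231, for apoptosis (-0.0041) and lysosome (-0.011) in MDA-MB-436, and for G2/M (0.047) with Fn14 against untreated in MDA-MB-436. Without the 3 arrays camera's direction for the interferon list turned, with medians of -0.0078 with GL2 and -0.057 with Fn14 against untreated in MDA-MB-436, and without MDA-MB-436 replicate 2 the direction for oxidative phosphorylation turned in untreated cells, with a median of -0.21 (0.31 without replicate 1).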

Other observations

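The tests of the label of whole arrays, of mixed cultures, of an exchange of labels and of direct siRNA action were chosen after the results were seen.

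The untreated profiles fell into sets of 5 and 3 arrays, and 3 of the 8 arrays were labelled otherwise than most arrays of their set. A mixture of both lines is argued against, since the share of the labelled line's own profile on these arrays was at most 0.0029 as a median over genes. A single exchange between an array of each line cannot account for all 3 arrays, since 1 array was left without a partner. It could account for the MDA-MB-231 array together with either of the MDA-MB-436 arrays, and is not excluded for these. The hypothesis that the line of the whole array was recorded wrongly had the values it needs, as the siRNA RNA fell in the same set as the untreated RNA on 8 of 8 arrays. No biological explanation was tested, and the labels were kept.

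Against GL2 siRNA, genes such as RAC2, DAZAP2 and COPRS were lowered as far as TNFRSF12A. Action of the GL2 siRNA is argued against for the 47 genes lowered by over 0.5 as a set. Their median rise with GL2 siRNA was 0.0985 of the size of the median difference (95% interval -0.011 to 0.149 from resampling the genes). That interval takes the genes as independent and leaves out the spread between arrays, and the rise is confounded with the dye. Action of the GL2 siRNA is not excluded for single genes, as IL6 and TNFRSF12A itself were higher with GL2 siRNA than in untreated cells. Loss of signalling from the receptor to NF-kB stays open, with a camera p of 0.265 and a list median of -0.045. That median met the bound set against it by less than its spread over genes (95% interval -0.082 to -0.006, also from resampling the genes). Direct action of the Fn14 siRNA on other transcripts stays open too: 83.9% of the genes called by over 0.5 were lower (47 of 56, exact 95% interval 71.7 to 92.4), and 63 were lower and 42 higher from the scanner's log ratio, but 6 were lower and 253 higher with median centring, where all 47 stayed below 0 (median -0.36). With 1 siRNA per target, effects of the receptor and of the siRNA cannot be told apart for these genes.

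Changes against untreated were in part shared by arrays of both labels, as log ratios of any 2 arrays correlated across genes at 0.237 to 0.847. Each label holds arrays of both profile sets, so this does not show that the lines share the changes. A bias of single probes between the dyes is argued against as the sole source of the changes, for the 56 genes called with GL2 siRNA that had other probes. Of these probes 73.8% had the same sign (48 of 65, exact 95% interval 61.5 to 84.0). Such a bias in a part of the genes is not excluded. A response of the cells to transfection stays open, since the smallest adjusted p among the interferon, NF-kB, ATF4 and heat shock lists was 0.146 with an estimated correlation, while each of the 4 had a camera p under 0.05 with the preset correlation in a labelled line. The dye was never exchanged, so a dye effect on whole transcripts cannot be told apart from the treatment.

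Of the 35 splits of the 8 arrays into 4 and 4, each fitted as 4 arrays against 4, 1 gave as many genes as Fn14 against GL2, the real split with 542, and the highest other gave 1. The weak correlations of the replicate numbers do not settle a pairing, and MDA-MB-231 replicate 2 joins arrays of different profile sets. If the numbers are taken to pair the arrays all the same, the splits to compare are the 8 that part all 4 pairs. There the highest other gave 0 genes, and 8 are too few for a share under 0.05, while the 27 that part fewer pairs gave at most 1. For the labelled lines in siRNA against untreated, the real count was 0, so 35 of 35 splits gave at least as many whatever the values, and this tests nothing (highest other 542, the split by siRNA). For gene lists between Fn14 and GL2, 4 of 35 splits gave at least the real 5 and the highest other gave 8, so chance cannot be excluded (of the 8 splits that part all 4 pairs, the highest other gave 4).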
